A study of Arabidopsis thaliana with 16 samples.

How the data were processed

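Total RNA from leaves was labelled with Cy3 and hybridised to 16 single-colour Agilent arrays of an Arabidopsis design, 4 arrays in each of 4 groups. The authors scanned the arrays and extracted the spots with Agilent Feature Extraction 9.5.3.1. Per the file headers, the processed signal of each spot is an intensity, background-subtracted and detrended within the array, with no normalization between arrays. The deposited scanner files also hold the raw mean signal and local background as intensity, and other columns with flags of 0 or 1 for spots well above background, saturated or not uniform. The deposited series matrix holds log2 values whose making the labels do not describe. Checked against the scanner files, they equal the log2 processed signal relative to the 75th percentile of each array, centred per probe, with r above 0.999 on every array.

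The processed signal was read in R 4.3.3 (with the data.table package, version 1.17.8), log2 transformed, and set relative to the 75th percentile of the 43803 spots that were not controls, and replicate spots of a probe were averaged. Spots marked as not uniform or as outliers of their probe were left out, 58 missing values after this step among the genes tested. Of 43603 probes, 38413 name a locus, covering 29030 loci, and 5190 name none. Each locus was represented by the probe with the highest mean over all 16 arrays, and was tested if that probe was well above background on at least 3 of 4 arrays of at least 1 group. That left 21051 loci, of which 8868 have a symbol and 20821 match a locus of the reference table. The median local background of an array averaged 47.4 to 52.2 within the groups, and the median processed signal of an array was 237 to 365. The number of arrays limits the precision, with a median standard error of 0.078 (log2) for the difference of a treatment and its control and 0.11 for the difference of responses. No spot was saturated on any array.

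A model with 1 mean per group was fitted to all 16 arrays with limma 3.58.1 (lmFit and eBayes, 12 residual and 1.85 prior degrees of freedom), 2-sided. A gene passed, and is said to have risen, fallen or been called, at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested and a difference of at least 2-fold (log2 of 1). The comparisons were severe heat minus its control, triple stress minus its control, the difference of these differences (triple minus heat), and the triple experiment control minus the heat experiment control. Errors are limma standard errors of the log2 difference unless stated otherwise. A fold against a group well above background on 0 arrays is given as a bound, with each array of that group set to its own signal or to the lowest signal well above background on it, whichever was higher. For named genes with some arrays below this floor, values with the floor use the same rule on all 16 arrays and carry no test. The overlap of both treatments was set against independent lists of the same sizes.

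The 21 gene lists (437 members, 420 measured) were fixed before the data were examined, as were the tests, the rule for named genes and most alternatives. Some members were written from general knowledge, with no annotation source to check membership against, which bears on every list count and median. Lists were tested with camera at a preset correlation of 0.01 and called at an adjusted p under 0.05 over the 21 lists. Camera with an estimated correlation and fry were alternatives. Fry tests whether the genes of a list move, on balance, in 1 direction and does not compare them with other genes. Named genes are the 5 largest rises and 5 largest falls in each treatment (4 and 4 for the difference of responses, 3 and 3 between the controls) among called genes with a symbol that were well above background on at least 1 array of each group compared. Except for the difference of responses, all 4 arrays of 1 group also had to lie on the same side of all 4 of the other. Further named genes are the 2 leading members of each called list, up to 2 called members against it, and 14 genes chosen in advance, of which 12 were measured. Leading members did not have to pass the test.

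The alternatives were normexp background correction (offset 50), median, quantile and spike-in scaling, the series matrix values, no filter or a filter on all 16 arrays, the mean of the probes of a gene, trend and robust moderation, array weights, fitting the compared groups alone, other thresholds, the other or both control groups, leaving out genes called between the controls, triple stress against severe heat directly, and leaving out each array in turn. Spike-in scaling (7 probes), leaving out 2 arrays together and a fold threshold inside the test (limma treat at log2 0.5) were added after the data had been seen. The replicate number was tried as a block, because all groups carry numbers 1 to 4. It gave 5557, 3375, 2049 and 454 genes in the 4 comparisons. Residuals of arrays with the same number in different groups correlated at -0.0997 to 0.0750 over 24 pairs, 0 of them above 0.1, so the numbers were not treated as pairs. The number is also the position on the slide. Every other split of the arrays into groups of the same sizes, or a draw of 100, was run through the same fit.

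The pipeline was tested on simulated data, normal noise with the residual standard deviation of each of the 21051 genes around its heat experiment control mean, with 200 changed genes per comparison. Changes of log2 1.5, 2 and 3 were recovered in 88 to 100% of genes, those of 0.5 in 0%, which the 2-fold minimum of a call all but fixes, and 1 to 2 unchanged genes were called. A list shifted by 0.5 was called and 0 of 20 others were. The noise was drawn independently for each gene, while the estimated correlation within the lists reached 0.61. This run thus cannot show how often lists of correlated genes are called falsely. Probes without a locus took no part in the comparisons and are described among the additional observations. The age of the plants was left out of the model, because the labels of the controls contradict each other and age cannot be told apart from group.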

Results

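Leaf RNA of Arabidopsis thaliana, ecotype Columbia, was measured on 16 single-colour Agilent arrays in 4 groups of 4. Plants in severe heat were kept at 37 °C by day and 33 °C by night for 3 days. Triple stress plants carried turnip mosaic virus for 13 days, had reduced water for 5 days and were heated for 3 days, at a temperature the labels do not give. Each treatment had a control group of its own at 22 °C by day and 18 °C by night, called here the heat experiment control and the triple experiment control. Every replicate pooled leaves of 5 to 8 plants. The labels conflict on whether the heat or the triple control was 34 days old and which was 37 days old. They give severe heat plants as 34 and triple stress plants as 37 days old. They also put virus inoculation at day 21, which with 13 days of virus falls short of 37 if counted from the same start. Age is the same within a group, so it cannot be told apart from group and is not used as a term here. Each group of 4 lay on 1 slide, so slide and group cannot be told apart in any comparison, and no value within a slide can be had.

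Before scaling, the 75th percentile of signal lay between 1701 and 1806 in the heat experiment control, 2296 and 2535 in severe heat, 1747 and 1876 in the triple experiment control, and 2224 and 2407 in triple stress. Between 28177 and 31937 of 43603 probes were well above background on each array. Pearson's r across the 21051 genes tested, which are not independent replicates, was 0.985 to 0.996 within groups and 0.985 to 0.987 between arrays of both control groups. It was 0.909 to 0.920 between severe heat and its control, 0.942 to 0.951 between triple stress and its control, and 0.964 to 0.974 between severe heat and triple stress. The first principal component held 68.6% of the variance and parted all 8 treated arrays from all 8 control arrays, and the second, with 11.9%, parted severe heat from triple stress.

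**Figure D1:**
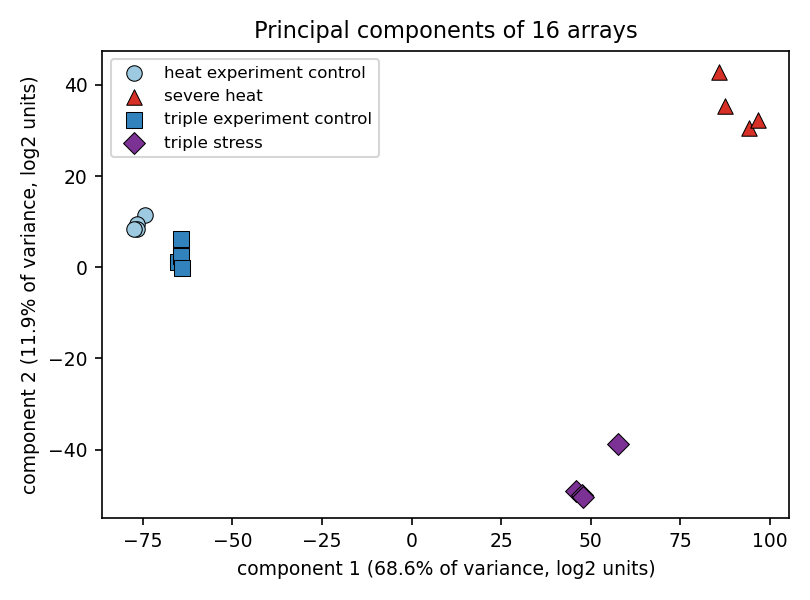
Scores of the 16 arrays on the first and second principal components (log2 units) of 21051 genes, each point 1 array coloured by group. The 4 severe heat arrays lie at 85.6 to 96.7 on the first axis and the 4 triple stress arrays at 45.9 to 57.5, while the 8 control arrays lie between -77.6 and -64.1.

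The first comparison asked what a single severe heat did to the leaf transcriptome. Heat shock proteins had the highest median difference of the 21 gene lists in severe heat, and photosystem genes the lowest. HSP23.6 (AT4G25200), a mitochondrial small heat shock protein, had a log2 difference of 10.29 ± 0.63 (standard error, n = 4 arrays per group), or 702-fold with arrays below the background floor set to it, since the control was well above background on 1 of 4 arrays. The log2 difference was 9.70 without heat experiment control replicate 3. HSP17.6C (AT1G53540), a cytosolic small heat shock protein, was 973-fold higher (9.93 ± 0.52). At the other end, LHCB2.4 (AT3G27690), a light-harvesting chlorophyll protein, was 15.1-fold lower (-3.92 ± 0.12), and WRKY54 (AT2G40750), a transcription factor of salicylic acid signalling, was 13.0-fold lower (-3.70 ± 0.24). In all, 5561 of 21051 genes (26.4%) passed the test, 2742 higher and 2819 lower.

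Other genes with the largest rises, as fitted, were LTP4 (AT5G59310), a lipid transfer protein, at 9.18 ± 0.73, KTI1 (AT1G73260), a trypsin inhibitor, at 7.44 ± 0.61, and SAG29 (AT5G13170), a sugar transporter associated with senescence, at 7.22 ± 1.02, each well above background on 1 to 3 of the 4 control arrays. With arrays below the background floor set to it, their differences were 8.64, 6.03 and 6.69. KTI1 and SAG29 then lay below HOP3 (6.97) and HSP23.5 (6.87), among others, so their places rest on signal below the floor. As fitted but without heat experiment control replicate 1, LTP4, KTI1 and SAG29 were at 9.82, 8.04 and 8.29 (7.58 for SAG29 with the floor), and without replicate 3 LTP4 was at 8.38 and SAG29 at 6.46. The largest falls were ARR15 (AT1G74890), a response regulator of cytokinin signalling, at -5.54 ± 0.19 (-5.31 with the floor), well above background on 1 severe heat array, and GolS3 (AT1G09350), a galactinol synthase, at -5.52 ± 0.27. PCC1 (AT3G22231) fell by 5.10, the cold-regulated chloroplast protein gene COR15A (AT2G42540) was at -4.82 ± 0.13 and the chloroplast fatty acid desaturase gene FAD8 (AT5G05580) at -4.58 ± 0.12. For these 10 genes all 4 severe heat arrays lay on the same side of all 4 control arrays, which was a condition of their choice. The probe for HSP23.6 covers chromosome 4 from 12917699 to 12917758 and that for LHCB2.4 chromosome 3 from 10258064 to 10258123, in the array files' own build (ath1:Jan2004).

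Of 32 measured heat shock proteins and co-chaperones, 28 rose and 1 fell, with a median log2 difference of 3.76 (camera adjusted p = 7.81e-08, and 0.497 as an adjusted p with an estimated correlation). HSP101 (AT1G74310), the disaggregase of acquired heat tolerance, was at 2.05 ± 0.23, while HSP70-3 (AT3G09440), a cytosolic chaperone, was the member that fell (-1.60 ± 0.18). Photosystem and light-harvesting genes were lower, with 24 of 43 past the test and a median of -1.06 (adjusted p = 5.31e-13, and adjusted p = 0.388 with an estimated correlation). PSAN (AT5G64040), a photosystem I subunit, fell by 2.05. Salicylic acid defence genes had 13 lower and 2 higher of 27, with a median of -0.85 (adjusted p = 0.0440, and adjusted p = 0.676 with an estimated correlation). ACD6 (AT4G14400), an ankyrin protein of this pathway, fell by 3.69, but PR2 (AT3G57260), a glucanase, rose by 2.50 ± 0.21 and PR5 (AT1G75040), a thaumatin-like protein, by 1.94 ± 0.31. The call of the salicylic acid list ended without any 1 of 6 arrays, with adjusted p from 0.0506 to 0.0698, namely heat experiment control replicate 4, severe heat replicates 1, 3 and 4, triple experiment control replicate 1 and triple stress replicate 4. It also ended under median scaling (adjusted p = 0.0611) and with signal above background on all arrays (adjusted p = 0.0584).

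In severe heat 5 more lists passed, none of them with an estimated correlation. RNA silencing genes had a median of 0.57 (adjusted p = 0.00671, and adjusted p = 0.388 with an estimated correlation), with 2 of 19 higher, AGO3 (AT1G31290) at 2.39 ± 0.26 and DCL3 (AT3G43920) at 1.08 ± 0.049, which missed the fold minimum with normexp background correction (0.93). Sugar starvation genes had a median of 0.42 (adjusted p = 0.0301, and adjusted p = 0.497 with an estimated correlation), with 4 of 14 higher, among them the amylase gene AMY1 (AT4G25000) at 3.15 ± 0.35 and the asparagine synthetase gene ASN1 (AT3G47340) at 3.13 ± 0.40. Calvin cycle genes had a median of -0.49 (adjusted p = 0.000789, and adjusted p = 0.388 with an estimated correlation), but 0.10 under quantile normalization and -0.011 under spike-in scaling, past the test in neither. The 2 of 13 that fell were HCEF1 (AT3G54050), a chloroplast fructose bisphosphatase, at -1.15 ± 0.045, and PRK (AT1G32060), phosphoribulokinase, at -1.11 ± 0.067, and neither passed under quantile normalization or spike-in scaling. Cytosolic ribosomal protein genes had a median of -0.36 (adjusted p = 0.00671, and adjusted p = 0.530 with an estimated correlation) with 0 of 26 past the test for single genes, where RPS6A (AT4G31700) was at -0.85 ± 0.080 and RPL10A (AT1G14320) at -0.81 ± 0.063, and the median turned to 0.12 under spike-in scaling. Under quantile normalization it was -0.074 and did not pass (adjusted p = 0.767). Guard cell markers had a median of -0.95 (adjusted p = 0.0429, and adjusted p = 0.530 with an estimated correlation), with 3 of 8 lower, led by GC1 (AT1G22690) at -2.81 ± 0.17 and the anion channel gene SLAC1 (AT1G12480) at -1.21 ± 0.096. SLAC1 missed the fold minimum against the other control group (-0.78), against averaged controls, with normexp background correction (-0.96) and with spike-in scaling (-0.73). The calls of the guard cell and sugar starvation lists ended against the other control group, with medians of -0.58 and 0.14. Both also ended against averaged controls, with medians of -0.77 and 0.24, and with signal above background on all arrays (adjusted p = 0.0584 and 0.0650), and the sugar starvation call with the mean of the probes of a gene (adjusted p = 0.0506).

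The other 13 lists did not pass in severe heat. Abscisic acid and drought genes had 16 higher and 6 lower of 48 (adjusted p = 0.0623), senescence and chlorophyll breakdown genes 6 and 1 of 12 (adjusted p = 0.106), and expansin and xyloglucan enzyme genes 1 and 7 of 19. Heat shock transcription factors had 4 higher of 18, unfolded protein response genes 2 of 18, clock genes 3 of 14 and aliphatic glucosinolate genes 1 of 17, with 0 lower in each. Jasmonate, ethylene and camalexin genes had 3 higher and 4 lower of 24, oxidative stress genes 4 and 4 of 24, and NLR resistance genes 1 and 3 of 19. Among markers of other cells or organs, floral genes had 3 higher and 1 lower of 6, genes of dividing cells 0 and 3 of 12, and phloem genes 0 and 0 of 7. The counts adjusted over the list alone were the same as those over all genes for each of the 21 lists. Median and mean differed in sign for the jasmonate and oxidative stress lists.

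Among genes chosen in advance, RD29A (AT5G52310), a drought and cold responsive gene, was at -3.26 ± 0.12, WRKY70 (AT3G56400) at -2.97 ± 0.28 and the defensin gene PDF1.2 (AT5G44420) at -3.97 ± 0.50 (-3.80 with the floor), while the jasmonate marker VSP2 (AT5G24770) was at 5.37 ± 0.76 (4.54 without severe heat replicate 3, which stood apart). HSFA2 (AT2G26150), a heat shock transcription factor, was at 0.39 ± 0.35, the argonaute gene AGO2 (AT1G31280) at -0.050 ± 0.19 and the Rubisco small subunit gene RBCS1A (AT1G67090) at -0.62 ± 0.066, none of them past the test. DREB2A (AT5G05410) at 0.89 ± 0.22 and NCED3 (AT3G14440), an enzyme of abscisic acid synthesis, at 0.88 ± 0.16 missed the fold minimum, though DREB2A passed it without severe heat replicate 3 (1.05) or 4 (1.01) and with array weights (1.01), and both passed it with spike-in scaling (1.38 and 1.36). PR1 and SAG12 were not tested, since their probes were too dim. Scaling to spike-in probes instead moved the median of all genes by 0.48 and gave 5371 higher and 1437 lower (78.9% higher, against 49.3%), so the directions above are relative to the bulk of the transcriptome.

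**Figure D2:**
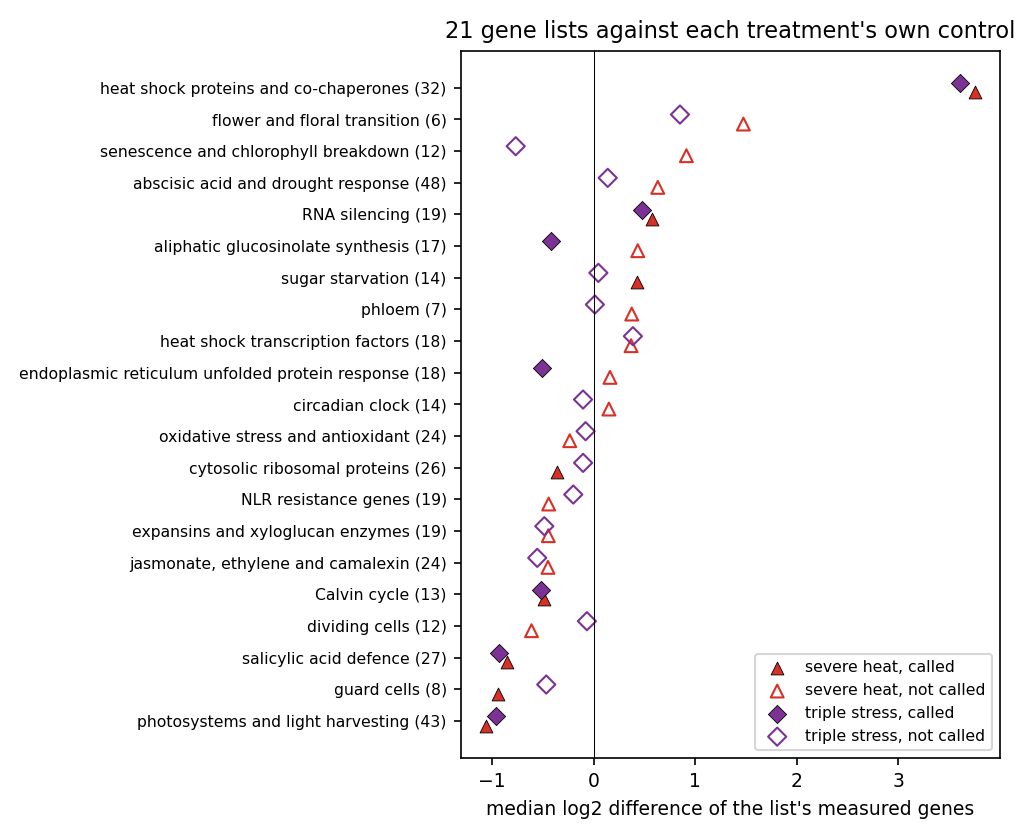
Median log2 difference of each of the 21 gene lists against the treatment's own control, with measured members in brackets, triangles for severe heat, diamonds for triple stress and filled symbols for lists past the camera test. The heat shock protein list stands at 3.76 and 3.61 and the photosystem list at -1.06 and -0.97, and quantile normalization turns the Calvin cycle medians, and spike-in scaling the ribosomal one in severe heat, above 0.

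The second comparison asked what virus, drought and heat together did, against the control of that experiment. Triple stress raised 24 of 32 heat shock proteins and lowered 18 of 43 photosystem genes, though neither list passed with an estimated correlation (adjusted p = 0.514 and 0.264). It lowered PR2, PR5 and the glutathione transferase genes GSTF2, GSTF3, GSTF6 and GSTF7. Unlike PR2 and PR5, the GSTF genes were lower in severe heat too, at -3.57, -3.47, -1.72 and, with the floor, -2.15 in that order. HSP17.6C was at least 765-fold higher and HSP23.6 at least 179-fold higher, counted against the background floor because neither was well above background on any control array. Without triple stress replicate 3 the bound for HSP17.6C was 1192-fold. BG3 (AT3G57240), a glucanase, was 78.0-fold lower (-6.29 ± 0.21), and PR5 was 8.55-fold lower (-3.10 ± 0.31, n = 4 arrays per group). In all, 3376 genes (16.0%) passed the test, 1749 higher and 1627 lower.

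The largest rises among genes measured in both groups were SAG29 (7.68 ± 1.02), the chaperone partner HOP3 (AT4G12400, 6.22 ± 0.16), the mitochondrial small heat shock protein HSP23.5 (AT5G51440, 5.69 ± 0.23), the glucosidase PYK10 (AT3G09260, 5.55 ± 0.53) and HSP18.2 (AT5G59720, 5.35 ± 0.39). SAG29 and PYK10 were each well above background on 1 control array, and with the floor their differences were 6.07 and 5.15. As fitted but without triple experiment control replicate 1, they were 8.60 and 6.15. After BG3, the largest falls were the glutathione transferases GSTF2 (AT4G02520, -5.77 ± 0.32) and GSTF3 (AT2G02930, -5.46 ± 0.28) and the cadmium resistance genes PCR1 (AT1G14880, -5.21 ± 0.50) and PCR2 (AT1G14870, -5.04 ± 0.48). In each of these 10 genes the 4 triple stress arrays did not overlap the 4 control arrays, again a condition of their choice. GolS3 was at least 49.8-fold lower, from 4 control arrays well above background to 0 triple stress arrays. The PR2 probe lies on chromosome 3 from 21199728 to 21199787 and the PR5 probe on chromosome 1 from 28182353 to 28182412.

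Heat shock proteins and co-chaperones had 24 higher and 1 lower of 32, with a median of 3.61 (camera adjusted p = 1.42e-08, and adjusted p = 0.514 with an estimated correlation). That median stayed the same with 8 members set to their bound against the background floor. HSP101 was at 2.13 ± 0.23 and HSP70-3 again fell (-1.48 ± 0.18). Photosystem genes had 18 lower of 43 and a median of -0.97 (adjusted p = 1.19e-16, and adjusted p = 0.264 with an estimated correlation), with LHCB2.4 at -2.40 ± 0.12 and PSAN at -1.75 ± 0.10. Salicylic acid defence genes had 12 lower and 1 higher of 27, with a median of -0.94 (adjusted p = 0.00192, and adjusted p = 0.650 with an estimated correlation). PR2 was at -2.89 ± 0.21, and the exception was WRKY40 (AT1G80840) at 1.13 ± 0.42. WRKY40 no longer passed without triple experiment control replicate 1 (1.04) or 3 (1.04), with normexp background correction (0.98), or without triple stress replicate 2 (0.82) or 4 (1.06).

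RNA silencing genes had a median of 0.48 (adjusted p = 0.00169, and adjusted p = 0.208 with an estimated correlation), with AGO3 at 2.03 ± 0.26 and DCL3 at 1.22 ± 0.049 the 2 of 19 that rose, though AGO3 missed the fold minimum under another background correction (0.92). Calvin cycle genes had a median of -0.52 (adjusted p = 4.20e-05, and adjusted p = 0.264 with an estimated correlation), with PRK at -0.94 ± 0.067, HCEF1 at -0.89 ± 0.045 and 0 of 13 past the test for single genes, though PRK passed under median scaling (-1.03) and with the mean of the probes of a gene (-1.14). The Calvin cycle median was 0.084 under quantile normalization. Unfolded protein response genes had a median of -0.51 (adjusted p = 0.0230, and adjusted p = 0.650 with an estimated correlation), with 2 lower and 1 higher of 18. BIP3 (AT1G09080), a lumenal chaperone, was at least 8.82-fold lower and the calreticulin gene CRT3 (AT1G08450) was at -1.67 ± 0.15, whereas NAC103 (AT5G64060) was at least 2.08-fold higher, a call lost under another background correction (0.32) and against the other control (0.93). Aliphatic glucosinolate genes had a median of -0.43 (adjusted p = 0.00726, and adjusted p = 0.650 with an estimated correlation), with SUR1 (AT2G20610) at -0.90 ± 0.066, MAM3 (AT5G23020) at -0.73 ± 0.19 and 0 of 17 past the test for single genes. Against the heat experiment control instead, the unfolded protein response and glucosinolate lists lost their calls, with medians of -0.31 and -0.11. Both calls were also lost under quantile normalization, with medians of -0.26 and -0.13 (adjusted p = 0.382 and 0.0994), and against averaged controls, with medians of -0.40 and -0.22. The unfolded protein response call was lost as well without replicate 1 of triple stress and of its control together (adjusted p = 0.0639).

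In triple stress 14 lists did not pass. Abscisic acid and drought genes had 14 higher and 7 lower of 48, jasmonate, ethylene and camalexin genes 5 and 8 of 24, expansin and xyloglucan enzyme genes 2 and 6 of 19, senescence genes 1 and 6 of 12 (adjusted p = 0.144), and oxidative stress genes 2 and 5 of 24. Heat shock transcription factors had 5 higher of 18, clock genes 2 of 14, NLR resistance genes 1 of 19 and genes of dividing cells 1 of 12, with 0 lower in each. Sugar starvation genes had 1 higher and 2 lower of 14, floral genes 3 and 1 of 6, guard cell markers 0 and 2 of 8, ribosomal protein genes 0 and 0 of 26 and phloem genes 0 and 0 of 7. For all 21 lists the counts adjusted over the list alone matched those over all genes. Median and mean differed in sign for the clock, phloem and dividing cell lists, and the sugar starvation test pointed down although median and mean were above 0.

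Of the genes chosen in advance, DREB2A (1.32 ± 0.22), HSFA2 (1.15 ± 0.35) and VSP2 (3.90 ± 0.76) rose, the rise of HSFA2 resting on triple stress replicate 1 (0.73 without it, and 0.79 without it and replicate 1 of its control). VSP2 was at 4.62 without triple experiment control replicate 1. RD29A fell (-3.48 ± 0.12), PDF1.2 was at least 6.02-fold lower, and NCED3 was at -1.34 ± 0.16 against its own control but at -0.017 against the other and -0.68 against both averaged, below the fold minimum in both. WRKY70 (-0.72 ± 0.28, or -0.36 without triple stress replicate 1), AGO2 (0.015 ± 0.19) and RBCS1A (-0.52 ± 0.066) did not pass. With spike-in scaling the median of all genes moved by 0.14, and 2265 genes were higher and 1274 lower (64.0% higher, against 51.8%).

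Both treatments changed many genes the same way. Of the triple stress calls, 75.4% were also called in severe heat in the same direction, 1357 higher in both and 1190 lower in both, together 2547 where independent lists of these sizes would share 445.7. HSP23.6, HSP17.6C, HSP101, HOP3 and AGO3 were among the genes higher in both, and LHCB2.4, PSAN, RD29A, GolS3 and COR15A among those lower in both. Across 21051 genes, which are not independent replicates, the differences had Pearson's r = 0.769 and Spearman's rho = 0.784. The triple stress difference was the smaller in 5012 of the 5561 genes called in severe heat, a share that choosing genes by severe heat raises. It was also the smaller in 2059 of the 3376 genes called in triple stress and in 9268 of the 14722 called in neither. In 61 genes both differences passed with opposite signs, 49 of them higher in severe heat and lower in triple stress, PR2 and PR5 among them.

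**Figure D3:**
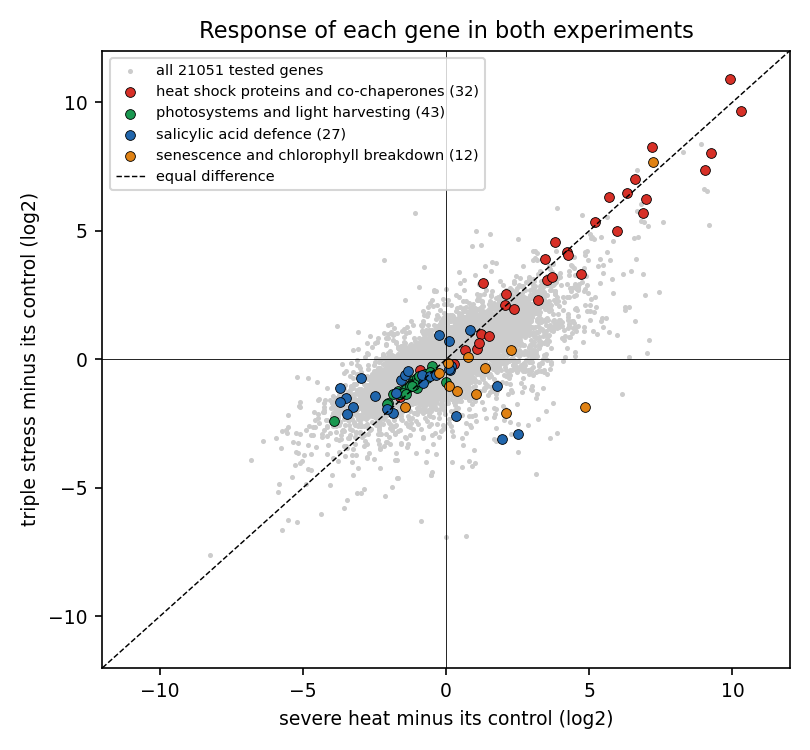
Log2 difference of each of 21051 genes in severe heat (horizontal) and triple stress (vertical), each against its own control, with 4 gene lists coloured and a dashed line of equal difference, drawn without the background floor. Heat shock proteins lie near the line, HSP101 at 2.05 and 2.13, while PR2 (2.50 and -2.89) and PR5 (1.94 and -3.10) lie below 0 in triple stress alone.

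The third comparison tested the difference of both responses, each taken against its own control. PR2, PR5 and the senescence gene SAG13 rose in severe heat and fell in triple stress. NAP did so against its own controls alone, since severe heat was -1.92 from the triple experiment control, and triple stress was 1.94 from the heat experiment control and -0.16 from severe heat. From the heat experiment control triple stress was -2.22 for PR2 and -2.85 for PR5. For SAG13 it was -0.44 as fitted and not called, in groups with few arrays well above background, so its fall did not hold against that control. PR2 went from 5.66-fold higher in severe heat to 7.41-fold lower in triple stress, a difference of -5.39 ± 0.30 (limma adjusted p = 2.76e-08), and PR5 differed by -5.04 ± 0.44. SAG13 (AT2G29350), a dehydrogenase associated with senescence, was 28.3-fold higher in severe heat and 2.38-fold lower in triple stress with arrays below the background floor set to it. Its controls were well above background on 2 and 3 of 4 arrays and triple stress on 1. As fitted, its fall in triple stress was not called with normexp background correction (-0.67) or against the heat experiment control. In the other direction, WRKY70 was 7.86-fold lower in severe heat and at -0.72 in triple stress (-0.36 without triple stress replicate 1, which stood apart), a difference of 2.26 ± 0.39. In all, 2056 genes (9.77%) passed, 1064 with a higher and 992 with a lower response to triple stress.

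As fitted, among called genes with a symbol that were well above background on at least 1 array of each of the 4 groups, the lowest differences were NATA1 (AT2G39030, an acetyltransferase) at -7.61 ± 1.38, ChlAKR (AT2G37770, a chloroplast reductase) at -6.78 ± 0.58, ELI3-2 (AT4G37990) at -6.74 ± 1.82 and SAG13 at -6.70 ± 0.69. Genes that this rule left out include RNS1 (AT2G02990) at -7.57 and LDOX (AT4G22880) at 6.05. ELI3-2 no longer passed under another background correction (-2.14). The highest by the same rule, as fitted, were RRTF1 (AT4G34410, a transcription factor) at 5.11 ± 1.75, XTH22 (AT5G57560, a cell wall enzyme) at 3.77 ± 0.60, NAC061 (AT3G44350) at 3.64 ± 0.80 and AGP17 (AT2G23130, an arabinogalactan protein) at 3.63 ± 0.34. For 6 of these 8 genes some arrays were below the background floor. With the floor the differences were -7.24 for NATA1, -6.25 for ChlAKR, -4.59 for ELI3-2, -6.07 for SAG13, 3.96 for RRTF1 and 2.48 for NAC061. ELI3-2 then lay behind BG3 and PR2 (each -5.39), and NAC061 behind bHLH38 (3.53) and PCC1 (3.45), so their places rest on signal below the floor. Leaving out 1 array moved some of the 8 differences by over 1.5 times, on both scales for NATA1 without heat experiment control replicate 1 (-8.43, or -8.05 with the floor) or severe heat replicate 3 (-6.62, or -6.25) and for ELI3-2 without heat experiment control replicate 1 (-7.99, or -5.42). As fitted only, ELI3-2 was at -7.79 without triple experiment control replicate 2, -6.14 without replicate 4 and -7.36 without triple stress replicate 3, and NAC061 at 4.34 without severe heat replicate 1. XTH22 fell in severe heat (-1.45, below the fold minimum at -0.97 with spike-in scaling) and rose in triple stress (2.32). RRTF1 passed with adjusted p = 0.0278, and its difference was 4.22 to 4.81 and no longer passed without any 1 of heat experiment control replicate 4, severe heat replicate 2 or 3, triple experiment control replicate 3 or triple stress replicate 2, 3 or 4. Of these, triple experiment control replicate 3 and triple stress replicate 3 moved it most (4.22 and 4.44), while it was 6.48 without triple stress replicate 1 (4.91 with the floor) and 5.77 without triple experiment control replicate 2. Positive differences also passed for ARR15 (2.66 ± 0.27, or 2.43 with the floor), PCC1 (3.45 ± 0.47), WRKY54 (2.59 ± 0.34), ACD6 (2.03 ± 0.21), FAD8 (1.94 ± 0.17) and SLAC1 (1.11 ± 0.14), all lower in severe heat. Negative differences passed for BG3 (-5.39 ± 0.30), KTI1 (-4.81 ± 0.86, or -4.34 with the floor), GSTF2 (-2.20 ± 0.46), GSTF3 (-1.99 ± 0.40), PCR1 (-2.24 ± 0.70), PCR2 (-2.17 ± 0.68) and HSP23.5 (-1.19 ± 0.32). Of these, KTI1 and HSP23.5 were higher in severe heat, while GSTF2 (-3.57), GSTF3 (-3.47), PCR1 (-2.97) and PCR2 (-2.87) were lower there as well as in triple stress. Without severe heat replicate 2, which stood apart for PCR1 and PCR2, their differences were -1.54 and -1.48. With normexp background correction neither PCR1 nor PCR2 passed (adjusted p = 0.0880 and 0.0716). KTI1 was at -5.40 without heat experiment control replicate 1. HSP23.5 missed the fold minimum without triple stress replicate 3 (-0.94), and SLAC1 with normexp background correction (0.85) and spike-in scaling (0.77).

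Senescence and chlorophyll breakdown genes responded lower in triple stress in 7 of 12, with a median difference of -1.37 (camera adjusted p = 2.80e-05), the only one of 21 lists to pass with an estimated correlation (adjusted p = 0.0273). Triple stress against severe heat directly gave this list a median of -0.41 that did not pass (adjusted p = 0.151), and between the controls it differed by 0.89. NAP (AT1G69490), a senescence transcription factor, differed by -4.19 ± 0.52. Abscisic acid and drought genes had 13 lower and 2 higher of 48 and a median of -0.45 (adjusted p = 0.000102, and adjusted p = 0.449 with an estimated correlation). LTP4 was at -3.97 ± 1.04 (-3.43 with the floor, and as fitted -4.61 without heat experiment control replicate 1 and -3.17 without replicate 3) and LTP3 (AT5G59320) at -3.52 ± 0.52, against CYP707A3 (AT5G45340), which breaks down abscisic acid, at 2.66 ± 0.62 and COR15A at 1.48 ± 0.19. Sugar starvation genes had 5 lower of 14 and a median of -0.85 (adjusted p = 0.000102, and adjusted p = 0.370 with an estimated correlation), with AMY1 at -2.30 ± 0.49 (-2.44 with the floor) and TPS11 (AT2G18700) at -1.73 ± 0.28. Unfolded protein response genes had 3 lower of 18 and a median of -0.67 (adjusted p = 1.23e-05, and adjusted p = 0.372 with an estimated correlation), with BIP3 at -2.61 with the floor (-1.89 without severe heat replicate 2), not past the test under another background correction (-1.19), and TMS1 (AT3G08970) at -1.68 ± 0.28. CRT3 (-0.75 ± 0.21) and NAC103 (-0.65 ± 0.16, or -1.02 with the floor) did not pass, except CRT3 with spike-in scaling (-1.09) and NAC103 in triple stress against severe heat directly (-1.15).

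Aliphatic glucosinolate genes had 4 lower of 17 and a median of -0.82 (adjusted p = 1.39e-06, and adjusted p = 0.372 with an estimated correlation), led by CYP79F2 (AT1G16400) at -1.91 ± 0.30 and the transporter gene BAT5 (AT4G12030) at -1.22 ± 0.15. Oxidative stress genes had 3 lower of 24 and a median of -0.23 (adjusted p = 0.0409, and adjusted p = 0.449 with an estimated correlation), led by GSTF7 (AT1G02920) at -2.35 with the floor, not past the test under another background correction (-1.05), and GSTF6 (AT1G02930) at -2.91 ± 0.52. The oxidative stress call ended without heat experiment control replicate 1, triple experiment control replicate 1 or 2 or triple stress replicate 3, with adjusted p from 0.0527 to 0.0738. It also ended with normexp background correction (adjusted p = 0.0887), without a filter on dim probes (adjusted p = 0.0620) and with signal above background on all arrays (adjusted p = 0.0553). Genes of dividing cells had 1 higher of 12 and a median of 0.60 (adjusted p = 0.0237, and adjusted p = 0.648 with an estimated correlation), with CYCB1;2 (AT5G06150) at 1.52 ± 0.30 and CYCB2;1 (AT2G17620), dim in 3 of the 4 groups, at 1.14 with the floor (0.44 without triple stress replicate 2). Without triple stress replicate 1, which stood apart for this list and CYCB1;2, they were at 0.78 and 1.77. Photosystem genes had a median of 0.17 with 1 of 43 higher (adjusted p = 0.00806, and adjusted p = 0.706 with an estimated correlation), led by LHCB2.4 at 1.52 ± 0.17 and PSAH2 (AT1G52230) at 0.54 ± 0.12. Ribosomal protein genes had a median of 0.26 with 0 of 26 past the test for single genes (adjusted p = 0.000205, and adjusted p = 0.449 with an estimated correlation), led by RPS6A at 0.55 ± 0.11 and RPL27AC (AT1G70600) at 0.52 ± 0.052. Spike-in scaling turned the photosystem median to -0.17 and the ribosomal one to -0.083.

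The other 12 lists did not pass in this comparison. Salicylic acid defence genes had 6 higher and 3 lower of 27, heat shock proteins 1 and 3 of 32, heat shock transcription factors 0 and 3 of 18, jasmonate genes 0 and 4 of 24, and expansin genes 2 and 1 of 19. NLR resistance genes and guard cell markers had 1 higher of 19 and 1 higher of 8, clock and phloem genes 1 lower of 14 and 1 lower of 7, and RNA silencing, Calvin cycle and floral genes had 0 of 19, 0 of 13 and 0 of 6 past the test. For the expansin list 4 genes passed when adjusted over the list alone, and for the other 20 lists the counts were the same. Median and mean differed in sign for the heat shock factor, salicylic acid, Calvin cycle and floral lists. HSP101 (0.082 ± 0.33), AGO2 (0.066 ± 0.27), RD29A (-0.22 ± 0.17), VSP2 (-1.47 ± 1.08, or -0.63 without severe heat replicate 3 and -0.75 without triple experiment control replicate 1), HSFA2 (0.76 ± 0.49), DREB2A (0.42 ± 0.32), PDF1.2 (-0.55 as fitted but 1.21 with the floor) and RBCS1A (0.095 ± 0.094) did not pass, except HSFA2 without triple stress replicate 3 (1.13, against 0.34 without replicate 1) and PDF1.2 in triple stress against severe heat directly (-1.40 as fitted, limma adjusted p = 0.0288), while NCED3 did (-2.22 ± 0.22). All triple stress arrays of PDF1.2 were below the background floor, so neither the size nor the direction of that direct difference can be read. Triple stress set directly against severe heat called 1159 of the 2056 genes the same way, and ended the calls of the abscisic acid (-0.12), oxidative stress (-0.16), senescence (-0.41), sugar starvation (-0.24) and dividing cell lists (0.40). It also ended those of HSP23.5 (-0.89), SLAC1 (0.68), NAP (-0.16), BAT5 (-0.79) and NCED3 (-0.89). Spike-in scaling moved the median of all genes by -0.34 and gave 438 higher and 1459 lower (23.1% higher, against 51.8%).

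**Figure D4:**
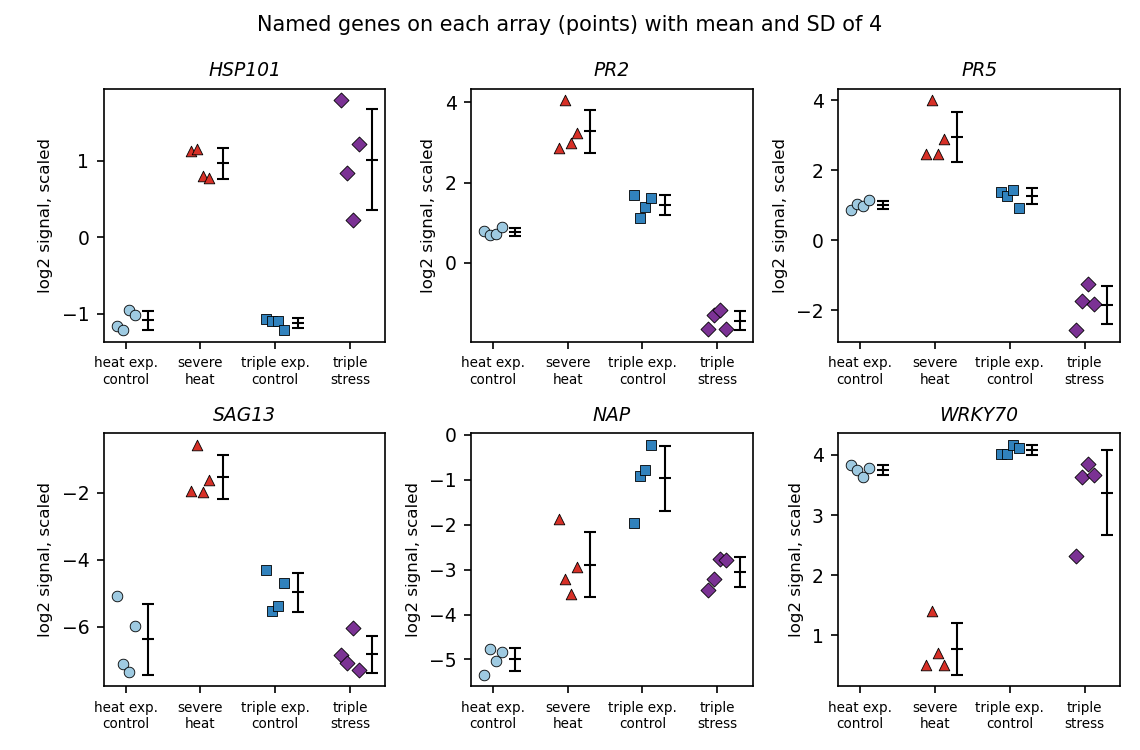
Scaled log2 signal of HSP101, PR2, PR5, SAG13, NAP and WRKY70 on each of the 16 arrays (points, by group) with the mean and standard deviation of 4 arrays beside them. PR2 has means of 3.27 in severe heat and -1.44 in triple stress, and SAG13 has means of -6.38 and -4.97 in the heat and triple experiment controls.

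The last comparison set both control groups against each other, since the third rests on their difference. Senescence genes were higher in the triple experiment control, 6 of 12 past the test. So were 8 of 48 abscisic acid and 3 of 14 sugar starvation genes, lists that did not pass with an estimated correlation (adjusted p = 0.226 for each), and spike-in scaling turned the sugar starvation median below 0. RNS1 (AT2G02990), a ribonuclease, was 40.6-fold higher there with arrays below the background floor set to it (log2 5.34), since 1 heat experiment control array was well above background, and NAP was 16.3-fold higher (4.03 ± 0.36). The iron deficiency regulators bHLH39 (AT3G56980) and bHLH38 (AT3G56970) were 4.69-fold (-2.23 ± 0.19) and 4.11-fold lower (-2.04 ± 0.12). In all, 455 genes (2.16%) passed, 312 higher and 143 lower in the triple experiment control, and 301 of the 2056 differences of responses were among them.

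ST2A (AT5G07010), a sulfotransferase of the jasmonate pathway, was at 3.29 with the floor, from 1 heat experiment control array well above background, NATA1 at 4.13 ± 0.97 (4.94 without heat experiment control replicate 1) and the response regulator gene ARR6 (AT5G62920) at -1.92 ± 0.23. These genes also carried large differences of responses, -4.74 for RNS1 and -2.88 for ST2A with the floor, 3.35 for bHLH39, 3.53 for bHLH38 and 2.51 for ARR6. Triple stress against severe heat directly called none of RNS1 (-0.90), ST2A (-0.77) and ARR6 (0.59), and ST2A did not pass with normexp background correction (-1.08). In triple stress RNS1 was at least 27.8-fold lower and ST2A at least 6.58-fold lower than the triple experiment control, but at -0.22 and 0.24 from the heat experiment control, neither called. Senescence genes had 6 of 12 higher and a median of 0.89 (camera adjusted p = 1.08e-05, and adjusted p = 0.0176 with an estimated correlation). Abscisic acid genes had 8 of 48 higher and a median of 0.37 (adjusted p = 2.17e-08, and adjusted p = 0.226 with an estimated correlation), LTP3 at 2.50 ± 0.36 and NCED3 at 1.33 ± 0.16 among them. Sugar starvation genes had 3 of 14 higher and a median of 0.22 (adjusted p = 0.000299, and adjusted p = 0.226 with an estimated correlation), which spike-in scaling turned to -0.046. Glucosinolate genes had a median of 0.28 (adjusted p = 0.000299, and adjusted p = 0.566 with an estimated correlation) and guard cell markers one of -0.41 with 1 of 8 lower, GC1 at -1.19 ± 0.17 (adjusted p = 0.00210, and adjusted p = 0.414 with an estimated correlation). Ribosomal protein genes had a median of -0.093 (adjusted p = 0.0243, and adjusted p = 0.755 with an estimated correlation) and expansin genes one of -0.30 (adjusted p = 0.0322, and adjusted p = 0.226 with an estimated correlation), with 0 of 26 and 0 of 19 past the test for single genes.

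Of the 14 lists that did not pass between the controls, salicylic acid and oxidative stress genes had 2 higher each, of 27 and 24, clock genes 1 of 14 and heat shock proteins 1 of 32, and the other 10 had 0 past the test. Adjusted over the list alone, 9 abscisic acid genes and 0 heat shock proteins passed, and the other counts were the same. Median and mean differed in sign for the NLR and clock lists, and the floral test pointed up although both were below 0. The ribosomal call ended without triple experiment control replicate 3 or 4 (adjusted p = 0.0546 and 0.0543) and the expansin call without heat experiment control replicate 2 or triple experiment control replicate 2 or 3 (adjusted p = 0.0557, 0.0591 and 0.0518). With the mean of the probes of a gene both ended (adjusted p = 0.0717 for each), and the ribosomal call also under quantile normalization (adjusted p = 0.0641) and spike-in scaling (adjusted p = 0.153). The majority of higher genes turned under spike-in scaling, with 149 higher and 377 lower after a median shift of -0.27, and under quantile normalization, with 233 higher and 278 lower (45.6% higher, against 68.6%).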

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

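Among the tests below, the ratio against averaged controls, the clock genes, the count of slides with more than 1 group, the genes of the same dim level, by either match, the split of the dimmer senescence genes by background, and the range over left-out arrays of the share still opposite were chosen only after a result they bear on had been seen.

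PR2, PR5, SAG13 and NAP are among 45 of the 78 named genes whose responses to severe heat and triple stress differed in the test of the difference itself, each treatment against its own control. The response to triple stress was the lower, in log2, for NATA1 (-7.61), RNS1 (-7.57), ChlAKR (-6.78), ELI3-2 (-6.74), SAG13 (-6.70), BG3 (-5.39), PR2 (-5.39), ST2A (-5.06), PR5 (-5.04), KTI1 (-4.81), NAP (-4.19), BIP3 (-3.98), LTP4 (-3.97), LTP3 (-3.52) and GSTF7 (-3.19). It was also lower for GSTF6 (-2.91), AMY1 (-2.30), PCR1 (-2.24), NCED3 (-2.22), GSTF2 (-2.20), PCR2 (-2.17), GSTF3 (-1.99), CYP79F2 (-1.91), TPS11 (-1.73), TMS1 (-1.68), BAT5 (-1.22) and HSP23.5 (-1.19). It was the higher for RRTF1 (5.11), XTH22 (3.77), NAC061 (3.64), AGP17 (3.63), bHLH38 (3.53), PCC1 (3.45), bHLH39 (3.35), ARR15 (2.66), CYP707A3 (2.66), WRKY54 (2.59), ARR6 (2.51), WRKY70 (2.26), ACD6 (2.03), FAD8 (1.94), LHCB2.4 (1.52), CYCB1;2 (1.52), COR15A (1.48) and SLAC1 (1.11). The lists that differed were senescence (-1.37), sugar starvation (-0.85), glucosinolate (-0.82), unfolded protein response (-0.67), abscisic acid (-0.45) and oxidative stress (-0.23) below 0, and dividing cells (0.60), ribosomal proteins (0.26) and photosystems (0.17) above 0. With spike-in scaling the ribosomal (-0.083) and photosystem (-0.17) medians were below 0. With an estimated correlation 8 of the 9 lists did not pass (adjusted p = 0.370 to 0.706), the exception being senescence (adjusted p = 0.0273). Triple stress against severe heat directly ended 5 calls, those of the abscisic acid, oxidative stress, senescence, sugar starvation and dividing cell lists, and those of ARR6, BAT5, HSP23.5, NAP, NCED3, RNS1, SLAC1 and ST2A. Without heat experiment control replicate 1 the differences as fitted were -7.99 for ELI3-2, -5.40 for KTI1, -4.61 for LTP4, -8.43 for NATA1 and -8.23 for RNS1, and without replicate 3 -3.17 for LTP4. They were 4.34 for NAC061 without severe heat replicate 1, -3.25 for BIP3 (-1.89 with the floor), -1.54 for PCR1 and -1.48 for PCR2 without replicate 2, and -6.62 for NATA1 without replicate 3. In the triple experiment, ELI3-2 was at -7.79 and RRTF1 at 5.77 without control replicate 2, RRTF1 at 4.22 without control replicate 3 and ELI3-2 at -6.14 without control replicate 4. RRTF1 was at 6.48 (4.91 with the floor) without triple stress replicate 1, and without replicate 3 ELI3-2 was at -7.36, RRTF1 at 4.44 and HSP23.5 at -0.94. Neither of the last 2 passed without it, and RRTF1 also did not pass without heat experiment control replicate 4, severe heat replicate 2 or 3, triple experiment control replicate 3 or triple stress replicate 2 or 4 (4.22 to 4.81). With arrays below the background floor set to it, the differences were -4.74 for RNS1, -2.88 for ST2A, -4.59 for ELI3-2, -2.61 for BIP3, 2.48 for NAC061, 3.96 for RRTF1, -2.35 for GSTF7, -6.07 for SAG13, -3.43 for LTP4 and -6.25 for ChlAKR, and moved by less than 0.5 for the other named genes listed here. Across all genes 2056 differed.

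Whether other groupings of the arrays give as much was counted. For severe heat 1 of 35 splits, the real one, gave 5561 genes and the highest other gave 1. For triple stress it was 1 of 35, with 3376 and 5, and for the controls 1 of 35, with 455 and 1. Of 100 splits, 1 gave as many genes changed in both treatments (2547, highest other 0) and 1 as many differences of responses (2056, highest other 1410). The other splits mix arrays of different groups, which puts the group difference into the residual spread and lowers these 5 counts. They are no measure of chance alone, here or for the lists below, and any difference between groups, slide effects included, would give this outcome. The split with 1410 kept all treated arrays in place and exchanged 2 arrays of each control group, so it keeps the difference between the treated groups. For how many lists passed, chance stays open, and the splits cannot decide it either way, since some keep part of the group difference. At least the 8 of severe heat were reached in 14 of 35 splits (highest other 12) and the 7 of triple stress in 13 of 35 (highest other 11). The 7 between the controls were reached in 9 of 35 (highest other 9) and the 9 of the difference in 24 of 100 (highest other 12).

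Triple stress changed fewer genes than severe heat, 3376 against 5561. Against the average of both control groups the counts were 3579 and 5352, a ratio of 0.669, which argues against the separate controls as the whole cause. Among the 10525 brighter genes the counts were 980 and 1962, a ratio of 0.499, which argues against dim probes near the background. With 0 slides that hold more than 1 group, slide effects cannot be told apart from the treatments. A heat regime of another strength in the triple experiment, whose temperature the labels do not give, the age of the plants and the added virus and drought also stay open, and were not tested.

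Senescence genes were higher in the triple experiment control, by a median of 0.89, and so were 8 of 48 abscisic acid genes, a list that did not pass with an estimated correlation (adjusted p = 0.226). Leaving out each of the 8 control arrays kept the senescence median between 0.77 and 0.94, which argues against a single array, and the 14 clock genes differed by a median size of 0.115, which argues against another time of day. A higher background floor goes with the test chosen in advance, where the 5 brighter senescence genes had a median of 0.15 against 1.41 for the 7 dimmer ones, with 96.2% higher among the 3837 genes called without a filter, and with the 2 dimmest spike-in probes, 1.46 and 1.25 higher before scaling where the other 8 were 0.23 to 0.35 higher. Against it, 689 other genes of that dim level had a median of -0.052 and 628 matched on the heat experiment control -0.040, and the 5 dimmer genes well above background on all 8 control arrays had a median of 1.62, so of the other 2 a higher floor stays open for SAG13, while SAG29 was not higher (-0.86, or 0.23 with the floor) unless heat experiment control replicate 1 is left out (0.21, or 1.12 with the floor). Age, which the labels give in conflict, may account for the pattern and stays open with the slide, since no test here parts them.

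In 61 genes the treatments went in opposite directions. Against averaged controls 59.0% of them (36, or 51.9% to 61.8% with 1 array left out) were still called opposite ways. Averaging leaves part of the control difference in both responses, so this does not exclude that cause for all 36. SAG13, 1 of them, was at -0.44 in triple stress against the heat experiment control. PR2 (2.17 and -2.55 against averaged controls) and PR5 (1.82 and -2.98) were also at -2.22 and -2.85 from that control in triple stress. Their controls differed by 0.67 and 0.24, which argues against the control difference as the cause for PR2 and PR5. It stays open for the others, NAP and NATA1 among them, and 25 of the 61 were called between the controls. NAP was at only -0.16 in triple stress against severe heat directly and at 4.03 between the controls, while NATA1 was at -3.49 and 4.13. Triple stress against severe heat directly called 56 of the 61 the way the difference went. Slide effects cannot be told apart from the groups, with 0 slides that hold more than 1. Neither can age, labelled 34 days in severe heat and 37 in triple stress, the latter in doubt from the day of inoculation. A response of PR2 and PR5 that virus or drought reverses is thus an open hypothesis. These data do not separate it from slide, age or another heat regime in triple stress, whose temperature the labels do not give.

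Single arrays far from the other 3 of their group, by Dixon's ratio of gap to range, were seen in 37 of 396 groups of named genes and list medians (9.34%), where chance at 1 in 20 gives 19.8. These groups are not independent of each other, so 19.8 is a rough guide. Some flags rest on signal below the background floor, such as that of RNS1 in severe heat replicate 2 (-9.04, with the floor at -6.89). Severe heat replicate 2 stood apart in 9: GSTF2 (0.830), GSTF3 (0.841), PCR1 (0.948), PCR2 (0.930), BIP3 (0.910), CRT3 (0.913), GSTF7 (0.853), GSTF6 (0.863) and RNS1 (0.868). Severe heat replicate 3 did so for HOP3 (0.872), NATA1 (0.848), LTP3 (0.858), VSP2 (0.947) and the floral list (0.844), replicate 1 for MAM3 (0.865) and replicate 4 for the expansin list (0.871). In triple stress replicate 1 stood apart for BAT5 (0.891), CYCB1;2 (0.850), WRKY70 (0.865) and the dividing cell list (0.838), replicate 3 for AMY1 (0.850) and NAC103 (0.880), replicate 2 for the abscisic acid list (0.940) and replicate 4 for the floral list (0.859). In the triple experiment control it was replicate 1 for SAG29 (0.880), GolS3 (0.906), FAD8 (0.941), the senescence list (0.991) and the glucosinolate list (0.900) and replicate 4 for LHCB2.4 (0.875), TMS1 (0.955), HSP101 (0.834) and the NLR list (0.832). In the heat experiment control it was replicate 1 for GSTF2 (0.930) and GSTF3 (0.873), replicate 3 for CYP79F2 (0.899) and replicate 4 for RRTF1 (0.874).

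Probes without a locus also carried signal: of 2973 that passed the filter, 384 were higher in severe heat than in its control (793 called) and 213 higher in triple stress (482 called).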

How the results depend on the processing

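Spike-in scaling, the fit without 2 arrays together and the test with a fold threshold inside it were chosen after the data had been seen, and the other alternatives before. All gene counts, numbers of called lists and the correlation of responses kept within 1.5 times the reported count, or for the correlation within 0.028 (1 standard deviation over 16 pairs of single treated arrays), under each alternative except those named here. The cause was not tested unless stated. Leaving out each array in turn gave 5479 to 5624 genes for severe heat, 3336 to 3421 for triple stress, 1988 to 2260 for the difference of responses, 427 to 515 between the controls and 2466 to 2587 in both treatments, correlations of 0.75 to 0.78, and 7 to 9, 7 and 8 to 11 lists.

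With normexp background correction 1826 genes passed in triple stress, 1159 in the difference, 180 between the controls and 1420 in both, and the correlation was 0.80. Without a filter on dim probes 3837 genes differed between the controls, 96.2% of them higher, 12 lists passed in severe heat and the correlation was 0.67. Requiring signal above background on all 16 arrays, which leaves fewer genes to test, gave 1353 differences of responses, 231 between the controls, 5 lists in severe heat and a correlation of 0.80. Without a minimum fold the counts rose by construction to 16654 in severe heat, 14994 in triple stress, 9608 in the difference, 6897 between the controls and 12337 in both. The test with a fold threshold inside gave 5216 genes in triple stress and 207 between the controls. Against both control groups averaged, which then share their error, the correlation was 0.83.

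Lists depended most on the test of the set. With an estimated correlation 0 lists passed in severe heat, 0 in triple stress and 1 in the difference, against 2, 3 and 2 at an unadjusted p under 0.05, while fry called 19, 17 and 13. Triple stress against severe heat directly gave 4 lists. Quantile normalization reversed the Calvin cycle medians to 0.10 in severe heat and 0.084 in triple stress. Spike-in scaling, which moves all genes up in severe heat and down in the difference and between the controls, turned the median of the ribosomal list to 0.12 in severe heat and -0.083 in the difference, that of the photosystem list to -0.17 in the difference, and that of the sugar starvation list to -0.046 between the controls. Over all alternatives, list calls stayed the same in 889 cases and were lost in 74 (29 of these with an estimated correlation). In 6 more the list median changed sign, which need not reverse the set test. Named genes, over all 4 comparisons, stayed the same in 9683, lost their call in 99 and gained it in 102. In 4 more cases a called gene changed sign, all against the other control group. NAP was then called the other way (-1.92 in severe heat and 1.94 in triple stress). NATA1 (-0.98 in severe heat) and ST2A (0.24 in triple stress) changed sign but were no longer called.

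With the replicate number as a block, 5557, 3375, 2049 and 454 genes passed, 2545 in both, and 9, 7 and 9 lists. Leaving out saturated genes was not run, since 0 spots were saturated. Dim signal limits folds for genes not above background in 1 group, which are given as bounds.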

Other observations

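The 5 gene groups here, made from the names and loci of the files, were chosen after the fixed lists had been tested and before their own values were seen, and the test of pseudogenes outside the AT2G07 loci was chosen after part of its result was known. Mitochondrion-encoded transcripts rose in severe heat, with 42 of 66 higher, 0 lower and a median of 1.96 (camera adjusted p = 7.21e-12, and adjusted p = 0.125 with an estimated correlation). ATMG01320, chosen after its values were seen, was at 6.93 ± 0.12 in severe heat. In triple stress 18 were higher and 1 lower, with a median of 0.48 (adjusted p = 0.000484, and adjusted p = 0.358 with an estimated correlation) that was 0.072 under normexp background correction. The response to triple stress was lower in 37 of 66, with a median difference of -1.43 (adjusted p = 5.23e-23, and adjusted p = 0.0173 with an estimated correlation), while 0 differed between the controls. The severe heat median was 1.08 with normexp correction and 2.44 with spike-in scaling.

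Chloroplast-encoded transcripts were lower, 21 of 66 in severe heat (median -0.84, and -0.36 with spike-in scaling or -0.50 under quantile normalization) and 15 of 66 in triple stress (median -0.70, and -0.36 under quantile normalization), with 0 higher in either and adjusted p of 9.90e-09 and 2.77e-09, or 0.295 and 0.358 as adjusted p with an estimated correlation. Between the controls their median was -0.29 with 0 called, and the set test passed there too (adjusted p = 1.09e-06, and adjusted p = 0.619 with an estimated correlation). Genes whose description names a core histone had 24 lower and 1 higher of 31 in severe heat (median -1.81, adjusted p = 1.39e-09, and adjusted p = 0.154 with an estimated correlation). Proteins that are not histones themselves may be among the 31, since descriptions were searched by name alone. The 1 higher member was AT4G14385 (1.44 ± 0.062), which was not checked for this. In triple stress 23 of 31 were lower (median -1.17, adjusted p = 3.00e-09, and adjusted p = 0.332 with an estimated correlation), and the response was higher in 11 (median difference 0.79, adjusted p = 1.90e-08, and adjusted p = 0.196 with an estimated correlation), a median that was 0.45 with spike-in scaling. The histone median between the controls was -0.32 with 0 called, again past the set test (adjusted p = 0.000629, and adjusted p = 0.619 with an estimated correlation).

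A hypothesis that severe heat activates transposable element genes as a group was not borne out, with 34 of 287 higher (11.8%) against 13.0% of other genes (Fisher's exact test, one-sided, p = 0.750) and 41 lower. That test does not speak to single elements. The largest rises were AT3G30843 (6.13) and AT1G21220 (4.76), well above background on 5 and 8 of 16 arrays, and the largest fall was Sadhu4-2 (-3.74). Pseudogenes were higher more often than other genes, 66 of 284 (23.2%) against 12.9% (Fisher's exact test, one-sided, p = 1.54e-06), a test that takes genes as independent. The set test did not pass for pseudogenes (median 0.093, adjusted p = 0.189, and adjusted p = 0.355 with an estimated correlation) or for transposable element genes (adjusted p = 0.588). The pseudogene median was -0.070 with normexp correction and 0.58 with spike-in scaling. Copies of mitochondrial DNA in chromosome 2 (loci AT2G07) could account for part of this, since 57 of 100 tested loci there were higher, 11 of its 21 pseudogenes among them. Without those loci 20.9% of pseudogenes (55 of 263) were still higher, which argues against them as the whole cause. Whether mitochondrial RNA binds to probes of such copies was not tested.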
